A study of Arabidopsis thaliana with 34 samples.

How the data were processed

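The series measured mRNA of whole aerial tissue from Arabidopsis thaliana seedlings 15 days old, grown on agar plates per the labels' protocols. Each sample was a pool of 5 to 15 seedlings of 1 genotype. The 9 genotypes were the inbred accessions C24, Ler and Col and the F1 hybrids of each pair in both directions (C24xLer and LerxC24, C24xCol and ColxC24, ColxLer and LerxCol). The labels do not say which name of a cross is the mother. There were 7 libraries each of C24 and Ler, 5 each of C24xLer and LerxC24, and 2 each of Col and of the 4 crosses with Col, 34 in all. The samples are lettered, A to G in the parents C24 and Ler and A and B in every genotype.

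Per the labels' protocols, total RNA was extracted with a column kit that included DNase digestion, and a service provider made TruSeq mRNA libraries and sequenced them as single-ended or paired-ended runs on GAIIx or HiSeq instruments. Which library was run in which way is not given in the sources used here. The authors deposited 1 table of raw counts per locus, whole numbers that are not normalized. TAIR10 and FastQC are named in the submitters' processing notes. The aligner, the counter, the treatment of read pairs and of strand, and their versions are not given in the sources used here. Because the use of strand is not stated, reads of overlapping or antisense genes cannot be told apart, and reads of near-identical copies could have been split or dropped. Counts of genes that differ in sequence or copy number between an accession and the reference can be too low in that accession.

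The table held 33321 loci, of which 32565 were matched by locus identifier to NCBI's TAIR10.1 annotation, used here for gene names and for overlaps between genes only. Of the 63 genes named by the rule given below, 12 overlap another annotated gene, and their counts are uncertain for that reason: FLC, AT2G11240, AT2G24760, AT3G44070, SADHU1-1, AT2G13970, AT2G09795, AT1G43910, BCA3, CBF3, DREB2A and HSP101. AOP2 and AOP3 are neighbouring copies of 1 gene, and their values are uncertain where reads match both.

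Columns were mapped to samples by their names. In 2 columns of LerxC24 the letter in the name is in no title of that group, so both were used as replicates of LerxC24 without a letter and are called U1 and U2. No column was left unmapped. No replicate pair agreed within sampling noise: over 67 pairs the lowest chi-square per gene was 24.9, where counting noise alone gives about 1.

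Total counts were 36324848 to 88686247 (median 79103874.5) in the 30 libraries not lettered C. The 4 libraries lettered C (C24, Ler, C24xLer and LerxC24), whose labels mention no read file, held 13198638 to 20435372 counts. In these 4, 11393 to 11692 loci were at 0 against 2066 to 2742 in the others, and 10296 loci were at 0 in all 4. Those 10296 loci included all 623 tRNA loci and 1017 loci with a mean above 200 counts in the other libraries. A count of exactly 1 was found at 0 to 6 loci per library of letter C and at 346 to 581 loci per library elsewhere. These libraries were kept, as fixed before the data were examined, and each count for C24, Ler and their hybrids was also made without them.

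Genes near 0 in an accession were used to check the libraries for RNA of another genotype. Such genes were chosen in letters A and B alone (at least 5 CPM in the accessions that express them and 20-fold less in the rest, settings loosened once because stricter ones left a set without genes, before any value was seen). For 17 genes expressed in C24 and Col and near 0 in Ler, the median level was 45.1% of that in C24 and Col in library Ler D and 34.2% in Ler E, against at most 0.739% in the other 5 Ler libraries. Each count for C24, Ler and their hybrids was therefore also made without Ler D and Ler E, an alternative chosen after seeing the data. In library LerxC24 B, 10 genes expressed in Ler alone had a median of 74.2% of their level in Ler and 18 genes expressed in C24 alone 31.9% of that in C24, against 48.3% to 60.3% and 30.4% to 51.3% in the other 4 LerxC24 libraries, and the fits that leave out 1 library include the fit without it.

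Tests were edgeR's quasi-likelihood tests (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM normalization, filterByExpr by genotype, robust dispersions and Benjamini-Hochberg adjustment over all genes tested, with calls at an adjusted p below 0.05. Comparisons within C24, Ler and their hybrids were fitted on their 24 libraries (29483 genes). Comparisons that involve Col or set families against each other were fitted on the 18 libraries lettered A and B of all genotypes (29777 genes). Hybrids of both directions were averaged and tested against the mid-parent, the mean of the parents on the log scale. A gene was counted as beyond both parents when it was called against each parent in the same direction. Log2 changes are given ± SE and levels as mean CPM ± SD. With 2 libraries per genotype, SDs of the Col families are rough. The p-values measure the spread between pools of seedlings, and nothing in the labels says that libraries of different genotypes or letters came from separate sowings.

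On the log scale the mid-parent of a gene with unlike parents lies below the mean of their levels, so an additive gene comes out as higher. In data simulated from these libraries, 500 additive genes above a set level were given strongly unlike parents and a capped spread. Smaller differences between the parents were not simulated. With limma-voom 495 of the 500 were called higher (median log2 1.09), and 0 when the mid-parent was the arithmetic mean of the parents' levels. That arithmetic mid-parent was tested with limma-voom (limma 3.58.1) and is given where it ends or turns the call of a gene named. Simulations of known changes were tested with edgeR. For C24, Ler and their hybrids, 16.4% of genes changed 1.5-fold, 43.3% of genes changed 2-fold and 72.7% of genes changed 4-fold were recovered. There were 2 false calls in a test of 29321 genes, the changed ones included. For the 18 libraries these shares were 47.8%, 86.6% and 97.0%, with 15 false calls. These simulations of known changes held no effect shared by libraries of a letter and no difference between the parents. They therefore cannot show how many calls in the data are false.

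The letters are shared between genotypes, so a fit with the letter as a block was planned as an alternative. Deviations from the genotype means were positively correlated across genes in all 26 pairs of same-lettered libraries of C24, Ler and their hybrids (lowest r = 0.600, median 0.750, against a median of 0.327 for pairs of other letters) and in all 72 pairs of the 18 libraries (lowest 0.212, median 0.389). In the 18 libraries the deviation of letter A mirrors that of B, so each correlation is counted in both letters. By the rule fixed for the block the letters pair the samples, and the blocked value is given where it changes a call or moves a count by more than 1.5 times. Without the libraries lettered C, 17 of 20 pairs were above 0.1 and the lowest r was -0.00664, so the bound of 0.1 was not met in every pair. The blocked fit of C24, Ler and their hybrids used the 22 lettered libraries. The estimated biological coefficient of variation was 0.501 for the 24 libraries, 0.275 without letter C and 0.151 with the block, and in the 18 libraries it was 0.165 and 0.106 with the block.

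Before the data were examined, 18 gene lists were fixed for the processes a seedling hybrid study would ask about, with root markers as a check of the tissue. Each was tested in each family with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the 54 tests, and again with an estimated correlation. None of the list calls held with an estimated correlation, where the lowest adjusted p was 0.0728. With fry, which asks only whether a list's genes move one way, the lowest-p lists are given in the text. Counts of members called are given over all genes and adjusted over the list alone.

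Genes are named by a rule fixed in advance: for parents and reciprocal crosses the 5 largest changes in each direction among genes called with a mean of at least 5 CPM, for mid-parent comparisons the 6 largest in each direction, up to 4 called members of each list and family, and 17 genes of defence, auxin, clock, cold and flowering in every family. Genes named outside this rule are said to be chosen after their values were seen. Alternatives were DESeq2 1.42.0, RLE normalization, no filter on counts, the replicate block, all 34 libraries in 1 fit, letters A and B only, no libraries lettered C, and leaving out each library in turn.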

Results

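Transcripts were counted in 34 libraries of aerial tissue from seedlings 15 days old: 7 each of the accessions C24 and Ler, 2 of Col, 5 each of the hybrids C24xLer and LerxC24, and 2 each of C24xCol, ColxC24, ColxLer and LerxCol. Total counts per library were 36324848 to 88686247, apart from the 4 libraries lettered C with 13198638 to 20435372. The series is about defence, stress and hormone networks and growth in F1 hybrids. The comparisons below ask which transcripts of a hybrid leave the level midway between its parents, which go beyond both parents, and whether the direction of the cross matters.

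**Figure D1:**
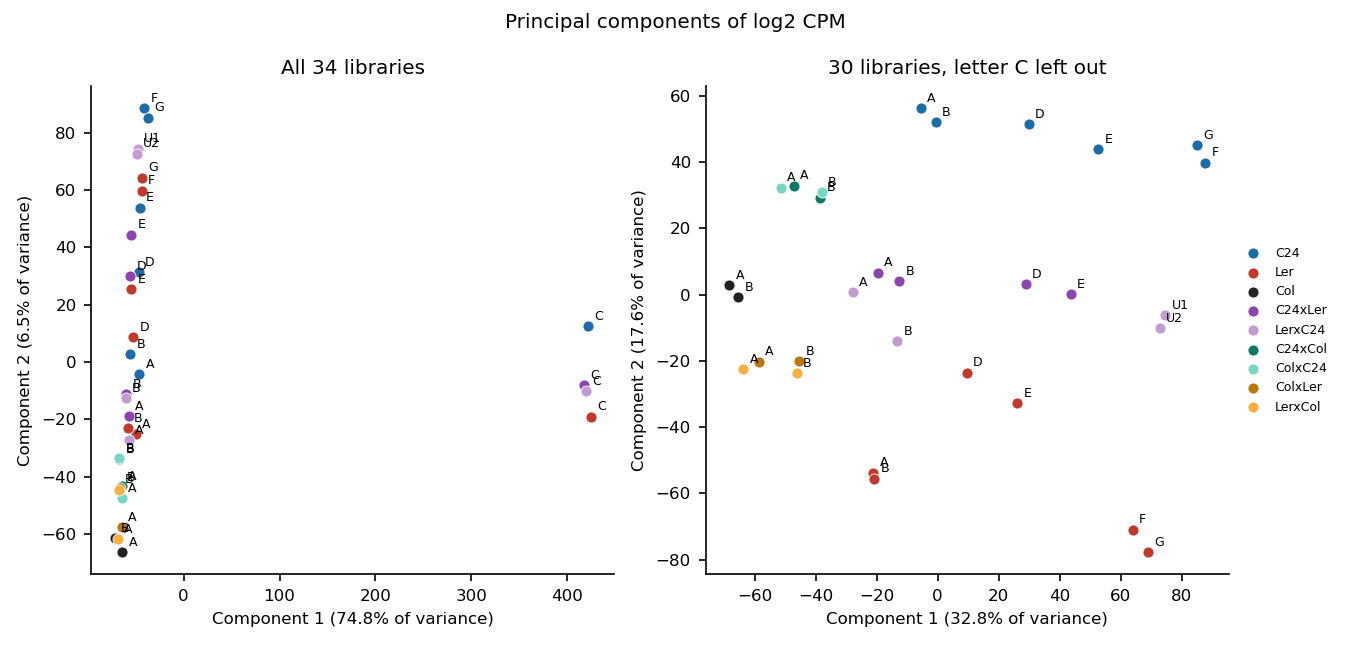
Principal components of log2 CPM, component 1 on the horizontal and component 2 on the vertical axis with their share of variance, for all 34 libraries and for 30 libraries without letter C, coloured by genotype and marked with their letter. Component 1 took 74.8% of the variance with letter C, whose 4 libraries lie alone at high values, and 32.8% without it.

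C24 and Ler seedlings differed most in genes that 1 accession barely expressed. C24 carried the floral repressor FLC at 68.1 ± 3.91 CPM (letters A and B, n = 2) where Ler had 0.688. It carried AOP2, an enzyme of alkenyl glucosinolate synthesis, at 555 ± 345 CPM (n = 7) where Ler had 2.95 ± 2.37. Ler carried AOP3, the neighbouring copy of AOP2 that makes hydroxyalkyl glucosinolates, at 179 ± 73.1 CPM where C24 had 0.953, and the arginase gene ARGAH2 at 117 ± 103.3 CPM where C24 had 0.212. In log2 units C24 exceeded Ler by 7.46 ± 0.84 for FLC (adjusted p = 2.04e-06; 6.52 without the libraries lettered C), 7.53 ± 0.68 for AOP2 (8.31e-08), 8.74 ± 0.46 for AT4G07965 (1.68e-11), 7.98 ± 0.31 for AT2G15160 (7.81e-14) and 7.62 ± 0.68 for AT4G08093 (6.58e-08). The changes on the Ler side were -8.99 ± 1.09 for ARGAH2 (6.08e-06), -7.52 ± 0.42 for AOP3 (2.98e-11), -7.34 ± 0.73 for AT2G24760 (3.61e-07), -6.72 ± 0.49 for AT3G44070 (2.38e-09) and -9.03 ± 2.30 for AT2G11240 (0.0193). AT2G11240 was lost with the letter as a block (adjusted p = 0.0569) and without Ler E (0.0572). It came to -0.31 (adjusted p = 1.00) without Ler D and Ler E, the libraries that hold transcripts near 0 in the other Ler libraries. Left-out libraries moved 3 of these values by over 1.5-fold in level: FLC came to 6.68 without C24 C, AT4G08093 to 8.90 without Ler D, and AT2G11240 to -10.09 without C24 B and -7.61 without Ler E. Of 29483 genes 1472 differed, 725 higher and 747 lower in C24. The count was 3943 without the libraries lettered C, 8840 with the letter as a block, 4794 with letters A and B alone, 1478 without Ler D and Ler E, and 2269 with DESeq2.

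C24 and Col differed in some of the same kinds of genes. ESP, which steers glucosinolate breakdown away from isothiocyanates, stood at 3496 ± 94.5 CPM in C24 and 42.1 ± 10.6 in Col (n = 2 each; log2 6.38 ± 0.19, adjusted p = 1.07e-09), and FLC at 68.1 ± 3.91 against 1.08 ± 0.307 (5.98 ± 0.20, 2.18e-09). AT2G13140 (7.51), AT5G28450 (7.15) and AT5G15360 (6.47) were the other largest on the C24 side. On the Col side these were SADHU1-1, a transposable element transcript (-10.51), AT2G11240 (-10.27), AT4G08110 (-9.72), AT2G13970 (-9.35) and AT4G07825 (-8.85). Adjusted p values of these 8 genes were 3.86e-10 to 0.000567. Without C24 B AT2G11240 came to -10.89 and AT4G07825 to -9.58. Of 29777 genes 3949 differed, 1664 higher and 2285 lower in C24, 6460 with the letter as a block and 1158 with all 34 libraries in 1 fit.

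Col and Ler differed in AT4G07825 and AT4G08110, which were at 0 in both Ler libraries, so that Col was at least 1164-fold and at least 954-fold higher (floor of 3 counts over the group). AT2G11240 (log2 10.37 ± 1.45, adjusted p = 0.000566), AT2G09795 (9.95 ± 0.37, 8.6e-09) and SADHU1-1 (9.75 ± 0.39, 1.43e-08) were also higher in Col. AT2G09795 came to 8.97 without Ler A and 13.10 without Ler B. AOP3 (-6.96 ± 0.45, 1.25e-06), ESP (-5.94 ± 0.19, 2.03e-09), AT5G27345 (-6.50), AT5G15360 (-6.43) and AT3G44070 (-6.08) were lower in Col. AT5G27345 came to -7.12 without Col B. In all 4143 genes differed, 2355 higher and 1788 lower in Col. The count was 7020 with the letter as a block, 683 with all 34 libraries in 1 fit and 2212 without Ler A.

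C24/Ler hybrids stood between their parents in 60 of the 71 genes that left the mid-parent in the 24 libraries, though not in most of the 614 called with the letter as a block. FLC was at 33.3 ± 2.54 CPM in C24xLer and 29.8 ± 3.49 in LerxC24 (letters A and B, n = 2 each), about midway between C24 and Ler in CPM and, for that reason, above the mid-parent in log2 units. MAF1, a relative of FLC that also represses flowering, was above both parents in mean CPM, with 29.6 ± 25.1 in C24xLer and 30.1 ± 25.1 in LerxC24 against 2.43 in C24 and 11.2 ± 13.6 in Ler. Letter C set that spread, and in letters A and B the levels were 15.8 and 15.3 against 2.16 and 6.01. Defence genes that respond to salicylic acid were lower as a list, and cold and drought genes, photosynthesis genes and auxin genes were higher as lists. These 4 calls were lost with an estimated correlation, in that order at adjusted p = 0.374, adjusted p = 0.283, adjusted p = 0.717 and adjusted p = 0.634. By the test 71 genes left the mid-parent, 69 above it and 2 below.

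Of the 69 genes above the C24/Ler mid-parent, 68 differed between the parents (median difference 5.50 in log2 units) and 60 lay between them. With the block 284 of 445 differed (median difference 0.56) and 181 lay between them, and 197 were also above the mean of the parents' CPM. AOP3 (3.29 ± 0.25, adjusted p = 8.95e-08), FLC (3.28 ± 0.51, 0.00134; 2.50 without letter C), AT4G07965 (3.18 ± 0.27, 4.89e-07), ARGAH2 (3.13 ± 0.62, 0.0229), AT2G24760 (2.86 ± 0.44, 0.00134), AT2G15160 (2.68 ± 0.18, 1.29e-08) and AOP2 (2.14 ± 0.40, 0.0106) belong there. Against the mean of the parents' CPM the same 7 genes came to 0.60, 0.32, -0.29, -0.50, 0.15, -0.33 and -0.54 in that order, and none of the 7 passed that test. With the block as well, AOP3 was 0.88 above that mean (0.0357). MAF1 passed both tests, by 2.53 ± 0.40 against the log-scale mid-parent (0.00177) and by 2.40 against the mean of the parents' CPM (0.0013). The 2 genes below were AT1G43910 (-0.92 ± 0.13, 0.00054) and AT2G32487 (-0.78 ± 0.13, 0.00326). AT1G43910 had 8.62 ± 1.61 CPM in C24, 14.0 ± 3.58 in Ler, 6.15 in C24xLer and 5.46 in LerxC24, and AT2G32487 had 16.6, 10.0, 9.17 and 6.11. Both passed against the mean of the parents' CPM too (0.013 and 0.042). ARGAH2 was lost without letter C (0.0833) and in the fits without C24 D, C24 E, C24 F, C24 G, C24xLer A, LerxC24 A or LerxC24 B (adjusted p up to 0.0574). The count of 71 became 187 without the libraries lettered C, 614 with the letter as a block (445 above and 169 below), 95 without Ler D and Ler E, 305 with letters A and B alone, 114 with all 34 libraries in 1 fit and 165 with DESeq2. With the arithmetic mid-parent it was 4 (2 above and 2 below), and 403 with the block as well (207 above and 196 below).

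Genes of salicylic acid synthesis and signalling did not move as a list in C24/Ler hybrids (median -0.06, adjusted p = 0.705), with ICS1 at -0.03 ± 0.19, PAD4 at 0.09 ± 0.21, EDS1 at 0.10 ± 0.15 and WRKY70 at -0.11 ± 0.31. The pathogenesis-related and salicylic acid-responsive genes were lower as a list (median -0.59, 14 of 21 negative, adjusted p = 1.54e-06), a call lost with an estimated correlation (adjusted p = 0.374). Of its members 0 passed over all genes and 2 were lower when adjusted over the list alone. PR1, the standard marker of salicylic acid response, averaged 169 ± 167 CPM in C24, 259 ± 182 in Ler, 20.5 ± 14 in C24xLer and 67.8 ± 112 in LerxC24, and its change of -2.48 ± 0.79 did not pass (adjusted p = 0.563). PR2 (-0.91 ± 0.38) and PR5 (-0.92 ± 0.43) did not pass either. Without Ler D and Ler E and with the block this list was no longer called (median -0.08, adjusted p = 0.0665), nor without letter C and with the block (median -0.32, adjusted p = 0.115).

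The abscisic acid, drought and cold list was higher in C24/Ler hybrids (median 0.44, 20 of 21 positive, adjusted p = 5.91e-11, and adjusted p = 0.283 with an estimated correlation), with 0 members past the test over all genes and 3 higher when adjusted over the list alone. The cold regulators CBF1 (1.74 ± 0.47, adjusted p = 0.258), CBF2 (1.27 ± 0.33, 0.202) and CBF3 (0.88 ± 0.62) did not pass. With the letter as a block CBF1 was 1.34 ± 0.28 (0.0214) and CBF2 1.09 ± 0.17 (0.00259). Photosynthesis and chlorophyll genes were higher by a small amount (median 0.22, 30 of 31 positive, adjusted p = 4.82e-05, and adjusted p = 0.717 with an estimated correlation), with 0 members called over all genes and 0 adjusted over the list alone. With the block these were 6 and 18, among them LHCA3 (0.38), PSBR (0.35) and PSBO2 (0.32). The auxin list was higher (median 0.20, 27 of 36 positive, adjusted p = 0.00236, and adjusted p = 0.634 with an estimated correlation), with 0 members called either way. The auxin synthesis gene YUC8 stood at 0.04 ± 0.29. The growth regulators IAA19 (0.32 ± 0.33), IAA29 (0.28 ± 0.41) and PIF4 (0.33 ± 0.31) passed with the block alone, at 0.49 ± 0.11 (0.0307), 0.62 ± 0.12 (0.0171) and 0.30 ± 0.06 (0.0255). Ethylene genes were higher (median 0.18, 15 of 19 positive, adjusted p = 0.00305, and adjusted p = 0.374 with an estimated correlation, 0 members called either way), a call lost without the libraries lettered C (0.161).

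Cell division genes were lower in C24/Ler hybrids (median -0.11, 15 of 16 negative, adjusted p = 0.0223, and adjusted p = 0.634 with an estimated correlation, 0 members called either way). So were floral organ markers (median -0.19, 8 of 8 negative, adjusted p = 0.000912, and adjusted p = 0.374 with an estimated correlation), though not with the block (0.0642). Of these 0 were called over all genes and 2 adjusted over the list alone. With the block 3 more lists were called: anthocyanin and flavonoid genes lower (median -0.47, adjusted p = 2.96e-08), and circadian clock genes (median 0.12, adjusted p = 0.00593) and gibberellin and brassinosteroid genes (median 0.08, adjusted p = 0.0373) higher. The clock genes CCA1 (0.26 ± 0.37) and LHY (-0.14 ± 0.27) did not pass.

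**Figure D2:**
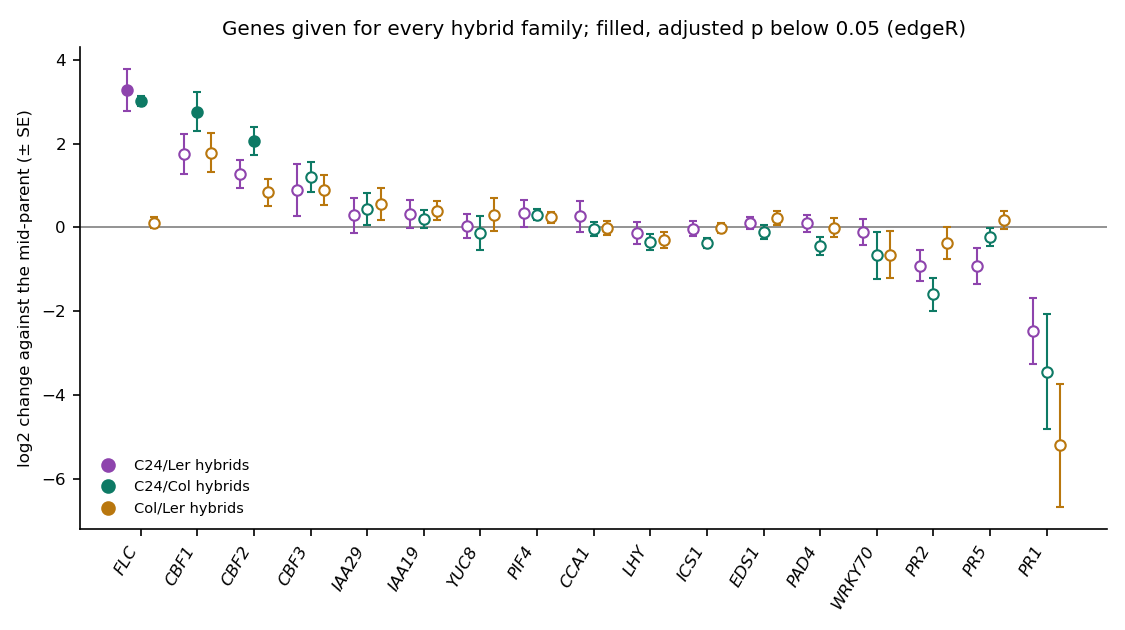
Log2 change of each hybrid family against the log-scale mid-parent (vertical axis, bars ± SE) for the 17 genes fixed in advance, C24/Ler on 24 libraries and the other families on 18, with filled points where the adjusted p of edgeR was below 0.05. FLC is filled in C24/Ler (3.28) and C24/Col (3.01), CBF1 (2.76) and CBF2 (2.06) in C24/Col, and the remaining points are open.

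C24/Col hybrids kept FLC at the level of C24: 67.9 ± 1.29 CPM in C24xCol and 70.5 ± 1.79 in ColxC24, against 68.1 ± 3.91 in C24 and 1.08 ± 0.307 in Col (n = 2 each). SOC1, a promoter of flowering that FLC represses, was at 14.7 ± 0.134 and 14.5 ± 1.72 CPM in the hybrids against 20.9 ± 0.72 in C24 and 85.2 ± 0.184 in Col. FUL, another promoter of flowering, was at 0.732 and 0.72 CPM against 0.978 and 4.75. The cold regulators CBF1 and CBF2 rose. Anthocyanin genes, cell division genes and salicylic acid-responsive defence genes were lower as lists, calls lost with an estimated correlation (adjusted p = 0.53, adjusted p = 0.49 and adjusted p = 0.49). By the test 369 genes left the mid-parent, 301 above it and 68 below.

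In log2 units FLC rose by 3.01 ± 0.12 against the C24/Col mid-parent (adjusted p = 1.32e-07) and by 1.00 against the mean of the parents' CPM (0.00196). SOC1 fell (-1.53 ± 0.14, 9.34e-05; -1.86 against the mean of the parents' CPM) and FUL fell (-1.57 ± 0.20, 0.00124). MAF1 rose on the log scale (1.15 ± 0.10, 5.69e-05) and stood between its parents in CPM, with 17.42 in C24xCol and 17.3 in ColxC24 against 2.16 and 28.3, so that against their mean it was at 0.19 and did not pass (adjusted p = 0.547). Of the flowering list (median -0.09, adjusted p = 0.832) 2 members rose and 2 fell over all genes, and 2 rose and 5 fell when adjusted over the list alone. CBF1 rose (2.76 ± 0.46, 0.0124), from 0.53 CPM in C24 and 0.973 in Col to 2.42 ± 0.382 in C24xCol and 9.72 ± 6.71 in ColxC24. CBF2 rose (2.06 ± 0.33, 0.00868), from 2.66 and 4.34 to 6.34 and 31.7 ± 24.6. CBF1 was lost without C24 B or C24xCol B (up to 0.0664) and CBF2 without C24 B or Col A (up to 0.0552). CBF3 (1.2 ± 0.35, adjusted p = 0.177) passed with the block alone (1.26 ± 0.28, 0.0228). The abscisic acid, drought and cold list to which these belong was higher (median 0.17, 16 of 21 positive, adjusted p = 0.000514, and adjusted p = 0.634 with an estimated correlation), with 2 members called over all genes and 3 adjusted over the list alone.

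The 6 largest rises on the log scale in C24/Col hybrids were in genes that 1 parent barely expressed: SADHU1-1 (4.53 ± 0.24, adjusted p = 1.01e-06), AT2G11240 (4.41 ± 0.81, 0.0219), AT4G08110 (4.07 ± 0.13), AT2G13970 (3.76 ± 0.25), AT4G07825 (3.54 ± 0.57, 0.0132) and AT1G76960 (3.304 ± 0.33, 0.000208). Of the 301 genes above, 257 differed between the parents and 229 lay between them, and 35 were also above the mean of the parents' CPM. With the block these were 632, 439 and 716 of 1248. AT2G11240 was lost without C24 A, C24 B, Col A, Col B, C24xCol A or C24xCol B (up to 0.154) and AT4G07825 without C24 A, C24 B or Col A (up to 0.0954). The largest falls after SOC1 were in the sugar transporter gene SWEET13 (-1.33 ± 0.24, 0.0175), AT3G05400 (-1.16 ± 0.24, 0.0385), the beta-glucosidase gene BGLU18 (-0.99 ± 0.16, 0.0067), AT1G20390 (-0.96 ± 0.07, 1.82e-05) and the phosphate transporter gene PHT1;4 (-0.87 ± 0.18, 0.036). SWEET13 was at 11.02 CPM in C24, 15.0 in Col, 5.68 in C24xCol and 4.63 in ColxC24, and BGLU18 at 489, 367, 236 and 192. SWEET13 was lost without C24 A, Col A, C24xCol A, C24xCol B or ColxC24 B (up to 0.0928), AT3G05400 in 15 and PHT1;4 in 12 of the 18 fits that left out 1 library (up to 0.181 and 0.158). Against the mean of the parents' CPM the 6 largest rises were at 0.27, 0.27, 0.21, 0.08, 0.11 and -0.01 and did not pass (adjusted p from 0.323 to 0.996). SWEET13 (-1.31, adjusted p = 0.0688), AT3G05400 (-1.24, 0.0654), PHT1;4 (-0.88, 0.0993), CBF2 (1.89, 0.0692), HSP101 (-0.44, 0.0988), TGG1 (0.30, 0.109), MYB12 (-0.61, 0.0792) and MAM3 (0.02, 0.970) did not pass that test either, and with the block as well the first 7 of these 8 did.

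Members of the heat shock list went both ways in C24/Col hybrids (median -0.14, adjusted p = 0.289; 1 up and 1 down over all genes, 1 up and 2 down adjusted over the list alone). DREB2A, a regulator of drought and heat response, rose (0.97 ± 0.14, 0.00371) and the chaperone gene HSP101 fell (-0.43 ± 0.09, 0.0476), the latter lost in 15 of the 18 fits that left out 1 library (up to 0.182). The gibberellin receptor gene GID1A rose (0.34 ± 0.06, 0.00769) and was the only member called in the gibberellin and brassinosteroid list (median 0.06, adjusted p = 0.267; 1 adjusted over the list alone). Of the glucosinolate list 4 rose over all genes and 5 adjusted over the list alone: ESP (2.20 ± 0.11, 4.67e-07), AOP2 (1.28 ± 0.20, 0.0074), MAM3 (0.69 ± 0.14, 0.03) and the myrosinase gene TGG1 (0.33 ± 0.06, 0.0276). Against the mean of the parents' CPM ESP was at -0.01 and AOP2 at -0.57. MAM3 was lost without C24 A, C24 B, Col A, C24xCol A, ColxC24 A or LerxCol A (up to 0.138) and TGG1 without C24 A, C24 B, Col A, C24xCol B, ColxC24 A or ColxC24 B (up to 0.152).

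The anthocyanin and flavonoid list was lower in C24/Col hybrids in all 14 members (median -0.91, adjusted p = 1.4e-05, and adjusted p = 0.53 with an estimated correlation). Over all genes 1 member passed, and 1 adjusted over the list alone: the flavonol regulator MYB12 (-0.60 ± 0.12, 0.0322), lost without C24 A, Col A, C24xCol B, ColxC24 A, ColxC24 B, LerxCol A or LerxCol B (up to 0.151). With the letter as a block 9 members were lower, among them PAP1 (-1.02), TT19 (-1.01), DFR (-0.95), LDOX (-1.18) and UF3GT (-1.53). Cell division genes were lower in all 16 members (median -0.29, adjusted p = 4.56e-07, and adjusted p = 0.49 with an estimated correlation, 0 called over all genes, 2 adjusted over the list alone). Floral organ markers were lower (median -0.16, 7 of 8 negative, adjusted p = 0.0433, and adjusted p = 0.374 with an estimated correlation, 0 over all genes, 1 adjusted over the list alone), though not with the block (0.112) or with all 34 libraries in 1 fit (0.278).

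The pathogenesis-related and salicylic acid-responsive list was lower in C24/Col hybrids (median -0.62, 18 of 21 negative, adjusted p = 7.48e-06, and adjusted p = 0.49 with an estimated correlation, 0 called over all genes, 2 lower adjusted over the list alone). PR2 (-1.59 ± 0.39, 0.0949), PR1 (-3.45 ± 1.37, 0.334) and PR5 (-0.22 ± 0.21) did not pass. The salicylic acid synthesis and signalling list was lower too (median -0.23, 15 of 21 negative, adjusted p = 0.0371, and adjusted p = 0.818 with an estimated correlation, 0 called either way), with EDS1 at -0.11 ± 0.17 and WRKY70 at -0.67 ± 0.56. ICS1 (-0.38 ± 0.12) and PAD4 (-0.45 ± 0.22) passed with the block alone (-0.38 ± 0.11, adjusted p = 0.049, and -0.47 ± 0.10, 0.0141). Photosynthesis genes were higher (median 0.12, 29 of 31 positive, adjusted p = 0.0108, and adjusted p = 0.861 with an estimated correlation, 0 called either way). The clock list (median 0.04, adjusted p = 0.209; 0 called either way) was called with the block (adjusted p = 0.00256). Of its members 8 were then higher, such as PRR5 (1.24), CCR2 (0.99) and FKF1 (0.99), and 4 lower, such as LNK1 (-0.44), RVE8 (-0.37) and LHY (-0.34, 0.0196; -0.36 ± 0.19 without it). CCA1 was at -0.04 ± 0.16, YUC8 at -0.13 ± 0.40, IAA19 at 0.20 ± 0.22 and PIF4 at 0.30 ± 0.13. IAA29 (0.44 ± 0.38) passed with the block alone (0.46 ± 0.12, 0.0412).

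The count of 369 genes against the C24/Col mid-parent was 2214 with the letter as a block (1248 above and 966 below), 786 with DESeq2, 75 with the arithmetic mid-parent (35 above and 40 below) and 1787 with that and the block (734 above and 1053 below). With all 34 libraries in 1 fit it was 35, and it was 236 without C24xCol B, 237 without C24 A and 666 without Col B.

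**Figure D3:**
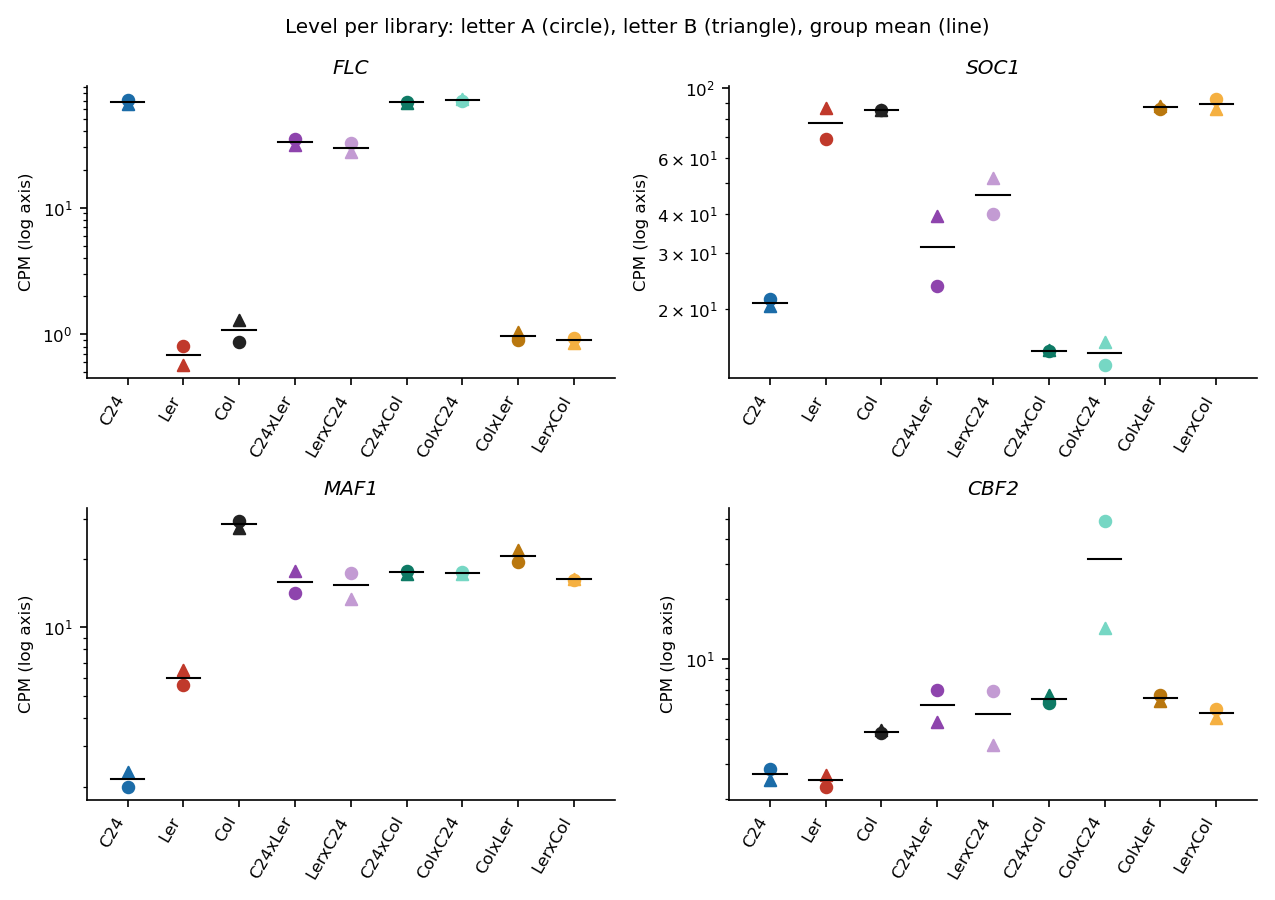
CPM per library on a log axis for FLC, SOC1, MAF1 and CBF2 in the 9 genotypes, letter A as circles, letter B as triangles and the mean as a line. FLC in C24xCol (67.9) and ColxC24 (70.5) lies at the level of C24 (68.1), while in C24xLer (33.3) and LerxC24 (29.8) it lies between C24 and Ler.

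Col/Ler hybrids shared the low FLC of both parents (0.11 ± 0.14 against the mid-parent). Their largest falls were in genes higher in Ler than in Col, and the hybrids stood near the level of Col. The beta-glucosidase gene BGLU28 was at 73.0 ± 5.56 CPM in Ler, 5.79 ± 1.79 in Col, 3.78 in ColxLer and 5.78 in LerxCol, the glutathione transferase gene GSTU24 at 24.2, 3.04, 2.84 and 3.48, and the floral gene SEP3 at 13.1, 1.40, 1.80 and 2.44. Heat shock genes were lower as a list, a call lost with an estimated correlation (adjusted p = 0.0728). By the test 334 genes left the mid-parent, 256 above it and 78 below.

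BGLU28 fell by 2.14 ± 0.31 on the log2 scale against the mid-parent (adjusted p = 0.00594), CYP81D8, a cytochrome P450 gene, by 1.70 ± 0.29 (0.0153), AT2G04050 by 1.47 ± 0.23 (0.00707), GSTU24 by 1.45 ± 0.23 (0.00738), the carbonic anhydrase gene BCA3 by 1.34 ± 0.20 (0.00577) and the metallothionein gene MT1C by 1.32 ± 0.24 (0.0194). SEP3 fell by 1.03 ± 0.15 (0.00381). CYP81D8 was lost without Ler A, Col B, ColxLer A, ColxLer B, LerxCol A or LerxCol B (up to 0.0937) and MT1C without Ler A, Col A, ColxLer A, ColxLer B or LerxCol B (up to 0.114). The largest rises were again in genes that 1 parent barely expressed. AT4G07825 (21.6 ± 1.4 CPM in Col, 0 in Ler, 10.8 in ColxLer and 9.35 in LerxCol) and AT4G08110 (17.7, 0, 9.75 and 7.75 CPM) are given by level because Ler was at 0. AT4G07825 was lost without Ler A (0.0685). AT2G11240 (4.33 ± 0.81, 0.026), AT2G09795 (3.91 ± 0.23, 2.81e-06), SADHU1-1 (3.83 ± 0.23) and AT1G35115 (3.80 ± 0.22) followed. Against the mean of the parents' CPM these 6 were at -0.11, -0.0271, 0.15, -0.0694, -0.0626 and 0.24 and did not pass (adjusted p from 0.743 to 0.970). AT2G09795 came to 3.42 without Ler A and 5.49 without Ler B, and AT2G11240 was lost in the 8 fits that left out a library of Ler, Col or their hybrids (up to 0.206).

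The heat shock list was lower in Col/Ler hybrids (median -0.29, 13 of 17 negative, adjusted p = 1.87e-06, and adjusted p = 0.0728 with an estimated correlation, and 0.00737 with fry), with 2 members down over all genes and 6 adjusted over the list alone. With all 34 libraries in 1 fit the list was not called (median 0.01, adjusted p = 0.461). The 2 members were HSP23.5 (-0.73 ± 0.13, 0.0181), lost without Ler A, Col B, ColxLer A or LerxCol A (up to 0.0988), and HSP101 (-0.50 ± 0.09, 0.0209), lost without Ler B, Col A, ColxLer A or LerxCol A (up to 0.105). Floral organ markers were lower (median -0.18, 7 of 8 negative, adjusted p = 0.000878, and adjusted p = 0.124 with an estimated correlation, and 0.0221 with fry), with SEP3 called over all genes and 2 members adjusted over the list alone. Cell division genes were lower (median -0.21, 15 of 16 negative, adjusted p = 0.00146, and adjusted p = 0.686 with an estimated correlation, 0 called either way). The anthocyanin list (median -0.33, adjusted p = 0.297) was called with the block (median -0.24, adjusted p = 0.0408).

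Auxin genes were higher in Col/Ler hybrids (median 0.20, 26 of 36 positive, adjusted p = 0.0223, and adjusted p = 0.49 with an estimated correlation, 0 over all genes, 2 adjusted over the list alone). YUC8 was at 0.30 ± 0.40, IAA19 at 0.40 ± 0.22, PIF4 at 0.24 ± 0.13 and IAA29 at 0.56 ± 0.38 (0.55 ± 0.12, adjusted p = 0.0228, with the block). Abscisic acid, drought and cold genes were higher (median 0.33, 17 of 21 positive, adjusted p = 0.00305, and adjusted p = 0.717 with an estimated correlation, 0 over all genes, 1 up and 1 down adjusted over the list alone). In it CBF1 was at 1.78 ± 0.47 (0.143; 1.82 ± 0.36, 0.0194, with the block), CBF2 at 0.83 ± 0.32 and CBF3 at 0.88 ± 0.36. Photosynthesis genes were higher (median 0.10, 24 of 31 positive, adjusted p = 0.0371, and adjusted p = 0.884 with an estimated correlation, 0 called either way). GID1A rose (0.29 ± 0.06, 0.0244), a call lost in the 8 fits that left out a library of Ler, Col or their hybrids (up to 0.121). It was the member called in the gibberellin and brassinosteroid list (median 0.08, adjusted p = 0.289; 1 adjusted over the list alone). MAF1 rose (0.49 ± 0.10, 0.035; lost in 11 of 18 fits, up to 0.195) and was the member called in the flowering list (median 0.05, adjusted p = 0.725; 1 adjusted over the list alone).

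Of the glucosinolate list 3 members rose in Col/Ler hybrids over all genes, TGG2 (2.54 ± 0.10, 8.58e-08), ESP (2.15 ± 0.11, 9.25e-07) and AOP3 (2.15 ± 0.26, 0.00145), and 4 rose and 4 fell when adjusted over the list alone. TGG2 was at 997 CPM in Col, 7.45 in Ler, 510 in ColxLer and 490 in LerxCol. Against the mean of the parents' CPM TGG2, ESP and AOP3 were at -0.01, 0.16 and -0.36 and did not pass. GID1A (0.28, adjusted p = 0.0742) and MAF1 (0.09, 0.823) did not pass that test either, and with the block as well GID1A did (0.28, 0.0072). With the block 6 members fell, among them the genes of aliphatic glucosinolate synthesis CYP79F1 (-1.20), CYP79F2 (-1.42), CYP83A1 (-0.71) and BCAT4 (-0.93). Salicylic acid genes did not move as lists (synthesis and signalling, median -0.01, adjusted p = 0.907; responsive genes, median -0.20, adjusted p = 0.307). Single members were ICS1 at -0.02 ± 0.12, PAD4 at -0.01 ± 0.22, EDS1 at 0.22 ± 0.17, WRKY70 at -0.66 ± 0.56, PR1 at -5.20 ± 1.47 (0.191), PR2 at -0.39 ± 0.38 and PR5 at 0.16 ± 0.21. CCA1 was at -0.01 ± 0.16, and LHY (-0.31 ± 0.19) passed with the block alone (-0.30 ± 0.08, adjusted p = 0.0476).

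Of the 256 genes above the Col/Ler mid-parent 245 differed between the parents and 222 lay between them, and 17 were also above the mean of the parents' CPM, while 65 of the 78 below were also below that mean. With the block 524 of 717 differed, 393 lay between and 236 were also above that mean, and 499 of the 541 below were also below it. The count of 334 was 1258 with the letter as a block (717 above and 541 below), 634 with DESeq2, 20 with all 34 libraries in 1 fit, and 98 with the arithmetic mid-parent (17 above and 81 below; 825 with the block, 242 above and 583 below). It was 187 without Ler A, 207 without ColxLer B, 211 without ColxLer A and 218 without LerxCol A.

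The lists not described for a family had these medians. Jasmonate genes were at 0.05 (mean -0.01) in C24/Ler, -0.04 in C24/Col and -0.02 in Col/Ler hybrids (adjusted p = 0.766, 0.472 and 0.659; 0 members called either way). Cell wall expansion genes were at 0.13, -0.07 and -0.04 (0.0639, 0.832 and 0.725; 0 called either way), the last with camera pointing up. Senescence genes were at 0.03 (mean -0.05), 0.01 and -0.14 (0.832, 0.684 and 0.725), with 0 called over all genes and, adjusted over the list alone, 1 down, 1 up and 0. Root markers were at 0.50, -0.12 and -0.36 (0.16, 0.582 and 0.297), with 0 called over all genes and, adjusted over the list alone, 1 up in Col/Ler hybrids. The glucosinolate list had a negative median and a test pointing up in every family (C24/Ler median -0.18, mean 0.11, adjusted p = 0.658; C24/Col median -0.15, mean 0.01, 0.145; Col/Ler median -0.28, mean -0.09, 0.204). In C24/Ler hybrids AOP2 and AOP3 rose over all genes and 2 rose and 2 fell adjusted over the list alone. The flowering list of C24/Ler hybrids (median -0.11, mean 0.08, 0.84) had FLC and MAF1 up over all genes, and 2 up and 2 down adjusted over the list alone. Without the libraries lettered C it was called higher (adjusted p = 0.0316) at a median of -0.11. For C24/Ler hybrids the remaining lists were heat shock (median -0.07 with the test pointing up, 0.945), clock (0.09, 0.242), gibberellin and brassinosteroid (0.06, 0.297) and anthocyanin (-0.21, 0.297), with 0 called either way. For C24/Col hybrids they were ethylene (0.03, 0.832; 1 up adjusted over the list alone) and auxin (0.02, 0.832; 0 called), and for Col/Ler hybrids ethylene (-0.03, 0.818) and clock (0.10, 0.553) with 0 called either way.

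**Figure D4:**
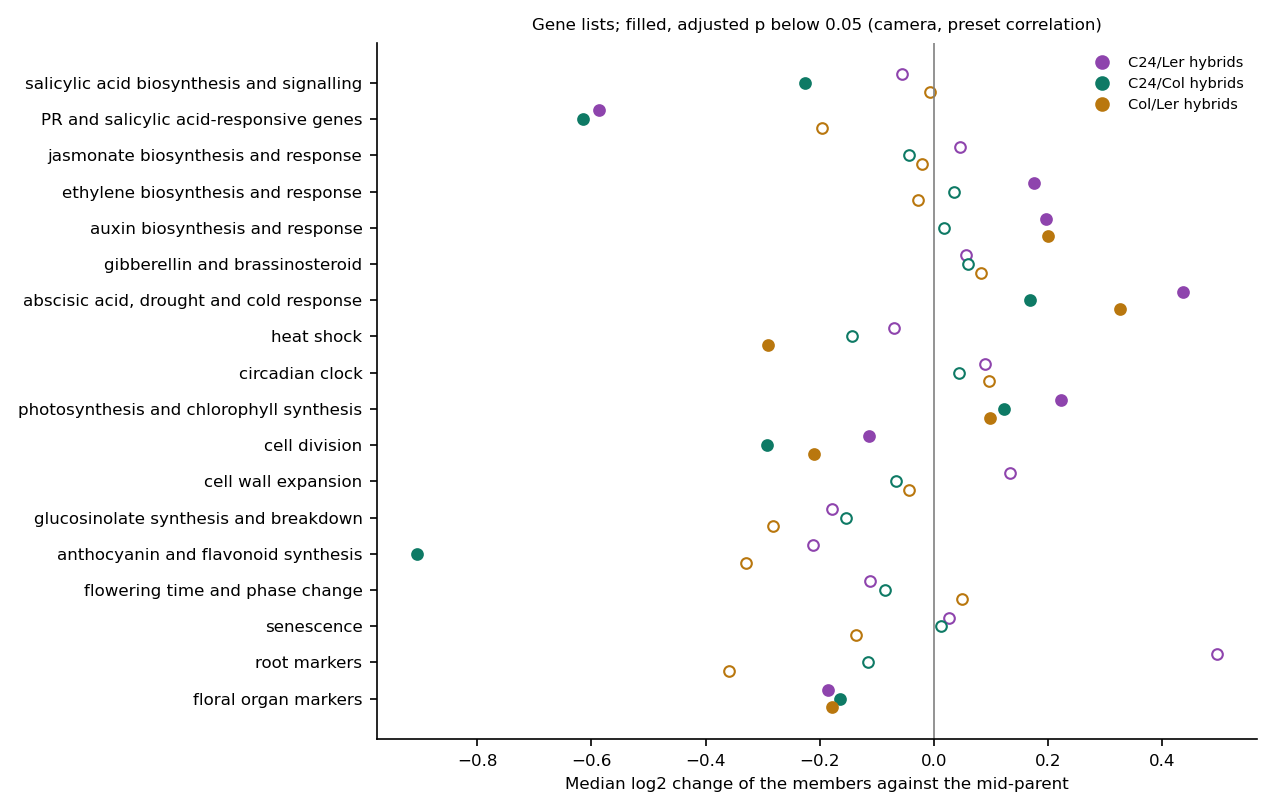
Median log2 change against the mid-parent (horizontal axis) of the members of the 18 gene lists in the 3 hybrid families, filled where camera with a preset correlation gave an adjusted p below 0.05. Photosynthesis and the abscisic acid, drought and cold list are filled to the right of 0 in the 3 families, and cell division and floral organ markers to the left.

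Beyond both parents, C24/Col hybrids had 24 genes above and 17 below. The genes named here and for the other families were chosen after their values were seen, apart from those named above. CBF2 was above C24 by 2.41 and above Col by 1.71 in log2 units, DREB2A by 0.95 and 0.98, GID1A by 0.35 and 0.34, the trichome regulator ZFP5 by 0.91 and 0.69, and KDR, a regulator of light signalling, by 0.67 and 0.47. TH8 was below C24 by a change of -1.88 and below Col by -1.41, BGLU18 by -1.20 and -0.79, SWEET13 by -1.10 and -1.55, the sulphate-reducing enzyme gene APR2 by -0.88 and -0.75, and HSP70 by -0.94 and -0.71. The count of 41 was 475 with the letter as a block (208 above and 267 below), 86 with DESeq2, 1 with all 34 libraries in 1 fit, 12 without Col A, 17 without C24 A, 18 without C24xCol B, 20 without C24 B or C24xCol A, and 63 without Col B or ColxC24 B.

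Col/Ler hybrids had 3 genes beyond both parents, AT5G57080 (-0.82 against Col and -0.65 against Ler) and BGLU11 (-0.35 and -0.46) below and AT1G64380 (1.17 and 0.91) above. The count was 155 with the block, 18 with DESeq2, and 1 to 14 in the fits that left out 1 library. It was 14 without Col B, 6 without ColxC24 A or ColxC24 B, and 1 without Ler A, C24xLer A, C24xLer B, C24xCol A, C24xCol B or ColxLer B. C24/Ler hybrids had 1, AT2G16140 (2.91 against C24, adjusted p = 0.00211, and 2.07 against Ler, 0.0459), at a very low level. In the fits that left out 1 library the count was 0 to 2 and changed in 20 of 24. It was 187 with the block (117 above and 70 below), 9 without the libraries lettered C, 3 with DESeq2 and 0 without Ler D and Ler E (182 with the block). The block added MAF1 (3.10 and 1.33), CBF1, CBF2, IAA19 and IAA29 above both parents.

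The families were compared with each other in letters A and B. The deviation of C24/Ler hybrids differed from that of Col/Ler hybrids in 122 genes (63 higher and 59 lower), among them FLC (2.09), AOP2 (2.67), MAF1 (1.62) and ESP (-2.25). With both deviations taken from the mean of the parents' CPM, a test chosen after seeing the data, 2 genes differed (7 with the block), 1 of the 122 among them: MAF1 (1.83, adjusted p = 0.000612), while FLC (-0.23), AOP2 (-0.07) and ESP (-0.28) did not pass (1.00 each). It differed between C24/Col and Col/Ler hybrids in 126 genes (72 higher and 54 lower), among them FLC (2.90), SOC1 (-1.64), FUL (-1.46) and TGG2 (-2.25). On the CPM scale 9 differed, all of them among the 126 (38 with the block), such as SOC1 (-1.98, 0.000981) and FUL (-1.85, 0.0186), while FLC (0.90, 0.317) and TGG2 (0.25, 1.00) did not pass. On the log scale the counts were 204 and 269 with the letter as a block, 212 and 263 with DESeq2, 16 and 9 with all 34 libraries in 1 fit, and the first fell to 78 without ColxLer B. MAF1 rose against the log-scale mid-parent in all 3 families (2.11, 1.15 and 0.49 for C24/Ler, C24/Col and Col/Ler), as did BBX17 (0.47, 0.63 and 0.55), OZF2, a zinc finger gene (0.69, 0.79 and 0.81), and BEE2, a brassinosteroid-responsive gene (0.35, 0.31 and 0.38). AO1 fell (-0.42, -0.41 and -0.42). In all 12 genes were called in 1 direction in the 3 families, 10 up and 2 down, 258 with the block (111 up and 147 down), and 226 with the arithmetic mid-parent and the block (57 up and 169 down).

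Pairs of families shared many calls, part of which can come from the parent they share. C24/Ler and C24/Col hybrids shared 98 higher and 12 lower genes (2.46 and 0.142 for independent lists), C24/Ler and Col/Ler 83 and 22 (2.09 and 0.16), and C24/Col and Col/Ler 122 and 7 (2.59 and 0.178). With the arithmetic mid-parent and the block most shared genes were lower: 128 higher and 339 lower, 67 and 319, and 161 and 271 in the same order, and with the block on the log scale 338 and 267, 246 and 252, and 384 and 264. With all 34 libraries in 1 fit 16, 5 and 10 genes were shared. In 20 simulations of hybrids set at the log-scale mid-parent of shared parents at most 1 gene was shared. Additive genes with unlike parents, which come out as higher on that scale, were not in these simulations. What share of the overlap and correlation they make up was therefore not tested. Across genes, which are not independent replicates, the changes correlated with r = 0.53, 0.51 and 0.58 against 0.253, 0.256 and 0.249 in the simulations. Their covariance exceeded the simulated one by 0.0441, 0.0411 and 0.0576. With no library shared, C24/Ler hybrids outside letters A to C (C24xLer D and E, LerxC24 U1 and U2) were set against the Col families of letters A and B. They shared 39 genes with C24/Col and 20 with Col/Ler hybrids (r = 0.25 and 0.11), and with letter C included 11 and 7.

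Few genes were called between reciprocal hybrids. In each pair the genes at an unadjusted p below 0.05 were fewer than the 1 in 20 that chance alone gives. Those numbers therefore show no signal beyond chance. Known changes were not simulated between reciprocal crosses, so few calls do not show that the crosses are alike. Between C24xLer and LerxC24 edgeR called 1 gene, the mitochondrial locus ATMG01170 (6.56 ± 0.93, adjusted p = 0.0356, at a very low level), with 93 genes at an unadjusted p below 0.05, 1 called by DESeq2 and 0 with the block. It was lost in 20 of the 24 fits that left out 1 library. Between C24xCol and ColxC24 edgeR called 0 genes (715 at an unadjusted p below 0.05) and DESeq2 19. With the block 5 were lower in C24xCol, ATAF1 (-0.74), AT1G64380 (-1.35), AT4G18422 (-1.93), AT5G24240 (-1.10) and AT5G50360 (-1.41), named after their values were seen, and without ColxC24 B 143 were called. Between ColxLer and LerxCol edgeR called 0 genes (1059 at an unadjusted p below 0.05), DESeq2 4, the block 0, and 1 was called without LerxCol B.

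In CPM, C24/Ler hybrids lay near the middle between their parents at genes that differ between C24 and Ler. A lean towards Ler was weaker without Ler D and Ler E and was then not seen in every hybrid library. Genes were chosen in some parent libraries and measured in others, and the median position was 0.512 (quartiles 0.389 and 0.605; 76 genes), where 0 is the lower and 1 the higher parent. Over the 10 hybrid libraries the median was 0.504 ± 0.0443 (mean ± SD), from 0.440 to 0.552. Genes higher in C24 had a median of 0.394 (35 genes) and genes higher in Ler 0.577 (41 genes), so on both sides the hybrids lay nearer to Ler. Without letter C these medians were 0.390 and 0.592. Library LerxC24 B stood apart on both sides, with medians of 0.262 for genes higher in C24 and 0.751 for genes higher in Ler. Without Ler D and Ler E the median position was 0.477 (61 genes), with 0.443 for genes higher in C24 and 0.538 for genes higher in Ler. In that setting C24xLer D, C24xLer E, LerxC24 U1 and LerxC24 U2 had the reverse order, such as 0.470 and 0.425 in C24xLer D. Genes higher in Ler were there below 0.5 in C24xLer A, B, D and E and above it in the other hybrid libraries. With all letters, Ler D was among the libraries that set the level of Ler.

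**Figure D5:**
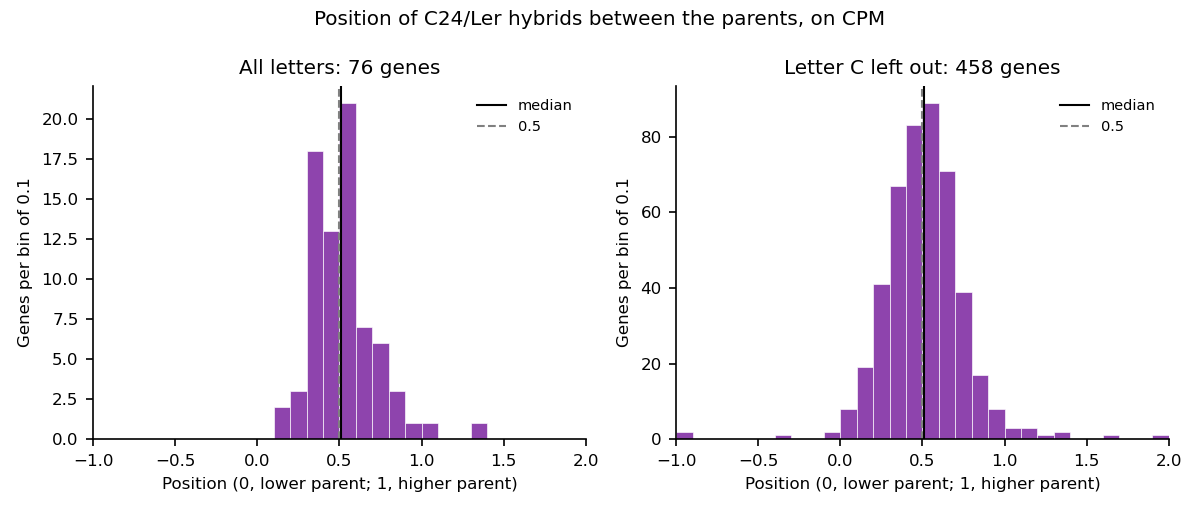
Number of genes per bin of 0.1 (vertical axis) by the position of C24/Ler hybrids between the parents in CPM (horizontal axis, 0 for the lower and 1 for the higher parent), for all letters (76 genes) and without letter C (458 genes), with the median as a solid line and 0.5 dashed. Both medians, 0.512 and 0.510, lie near 0.5; 2 genes below -1 are counted in the first bin and 1 above 2 in the last without letter C.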

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

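The tests by random splits of the libraries and the test of touch-responsive genes over the families were set before their results were seen, and the other tests in this part were chosen after. For the CBF genes, the test of whether the change depends on the letter was also reworded after its result was seen, with its bounds kept, and for touch-responsive genes in single families the spread was added to the bounds after the values were seen.

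Samples far from the rest of their group were found in 12 of the 48 groups of values tested, where chance gives about 1 in 20. Most were libraries lettered C. Their loci at 0 numbered 11685 in C24 C, 11692 in Ler C, 11393 in C24xLer C and 11464 in LerxC24 C, and the total count of C24xLer C was 19454776. FLC stood at 512 CPM in C24 C, 329 in C24xLer C and 336 in LerxC24 C, and AT2G24760 at 3.34 CPM in Ler C and 1.67 in C24xLer C. Outside letter C, AT2G32487 stood at 23.7 CPM in C24 E and PR1 at 267 CPM in LerxC24 U1.

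Deviations from the mid-parent that differed between families by the test of the difference were also picked out. Between C24/Ler and Col/Ler hybrids these were 122 genes, of the genes named AT2G15160 (2.84), AOP2 (2.67), FLC (2.09), ARGAH2 (2.95), AT2G24760 (2.90), MAF1 (1.62), ESP (-2.25), SADHU1-1 (-3.74), AT2G09795 (-1.52), AT1G76960 (-2.92), AT1G20390 (-0.64) and AT4G08110 (-5.68, a fitted value that rests on libraries at 0 and is no bound). Between C24/Col and Col/Ler hybrids these were 126 genes, of the genes named AT4G07965 (3.64), AT2G15160 (2.08), AOP2 (1.502), FLC (2.90), ARGAH2 (3.19), AT2G24760 (2.85), MAF1 (0.66), MAM3 (0.87), AOP3 (-2.15), AT2G09795 (-2.74), SOC1 (-1.64), AT1G20390 (-1.67), AT1G35115 (-3.68), FUL (-1.46) and TGG2 (-2.25). These differences are on the log scale, and with both deviations taken from the mean of the parents' CPM 2 and 9 genes differed, of the genes above MAF1 for the first pair and SOC1, FUL and AT1G20390 for the second.

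Most genes that left the mid-parent were above it, 97.2% in C24/Ler, 81.6% in C24/Col and 76.6% in Col/Ler hybrids, and with the letter as a block 72.5%, 56.4% and 57.0%. With the arithmetic mid-parent the highest share among the families was 50.0%, in C24/Ler hybrids with 2 genes above and 2 below. It was 46.7% in C24/Col and 17.3% in Col/Ler hybrids. This goes with the log scale as a source of the excess, though so few genes show no balance in C24/Ler, and the block alone lowered the share too. With the arithmetic mid-parent and the letter as a block the shares were 51.4% in C24/Ler, 41.1% in C24/Col and 29.3% in Col/Ler hybrids. These shares argue against hybrids as a class carrying more genes above than below the additive level. Single genes, such as MAF1 in C24/Ler and FLC in C24/Col hybrids, passed on both scales, and a biological difference in those genes stays open and untested.

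Few genes were called in the 24 libraries of C24, Ler and their hybrids for the size of their spread (coefficient of variation 0.501). Without letter C the count for C24 against Ler was 3943, and 3.13 times the highest count without any other letter (1259), which is consistent with another way of counting or filtering in those 4 libraries. Depth alone would leave few abundant loci at 0, while 1017 loci with a mean above 200 counts elsewhere were at 0 in all 4. The median correlation of libraries of 1 letter exceeded that of other pairs by 0.423, so a shared sowing, harvest or run per letter may add to the spread too. Random splits show the same structure: a split that put the 4 libraries lettered C in 1 parent group called 2803 genes.

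The values of CBF1, CBF2 and CBF3 were above the mid-parent in the 3 families, past the test without the block for CBF1 and CBF2 in C24/Col hybrids, with the block alone for CBF1 and CBF2 in C24/Ler, CBF3 in C24/Col and CBF1 in Col/Ler hybrids, and in neither fit for CBF3 in C24/Ler and CBF2 and CBF3 in Col/Ler hybrids. Touch-responsive genes had a median of -0.67 in Col/Ler hybrids (9 of 11 negative). By the bound set, this argues against handling at harvest as the cause in all families. The argument is weak, because the genes are not independent replicates and 0 of the 11 were called in any family by edgeR with the block. Medians were 0.53 in C24/Col (3 of 11 negative) and 0.25 in C24/Ler hybrids (2 of 11). There handling and a hybrid effect cannot be told apart, because neither median is past the bounds set by more than its spread over the genes. Without its highest letter the mean change was at least 0.76 in each family, so 1 letter alone does not carry it. In letter E of C24/Ler hybrids the mean change was -0.0284, so the change may depend on the letter. That value rests on 1 hybrid library and on Ler E, which holds transcripts near 0 in other Ler libraries. Evening clock genes exceeded morning ones by 0.30 in C24/Ler and 0.46 in Col/Ler hybrids, between the bounds set, and by 0.72 in C24/Col hybrids, past the 0.5 set for a difference in time of day, so harvest at another time of day and a hybrid effect on these genes cannot be told apart, because clock and cold genes both follow the time of day and the labels give no hour of harvest. The biological difference between hybrids and parents stays open and untested.

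Random splits into groups of the real sizes tested whether an arbitrary grouping of the libraries calls as many genes. For C24 against Ler 2 of 100 splits, the real one included, called as many genes (real 1472, highest other 2803), for the C24/Ler mid-parent 4 of 100 (real 71, highest other 2006), for genes beyond both parents 1 of 100 (real 1, highest other 0) and for C24xLer against LerxC24 2 of 100 (real 1, highest other 1). The first 2 counts pass the measure set for this test, because few splits called as many genes. Some splits called more genes than the real grouping, so an arbitrary grouping is not excluded. The splits mix parents and hybrids and so also remove the difference between C24 and Ler, which most genes above the mid-parent carry. They therefore do not test whether hybrids leave the mid-parent. The counts of 1 gene pass the same measure, but most fits that left out 1 library gave 0, and for C24xLer against LerxC24 the letters shared give too few splits within letters to exclude chance and the blocked fit called 0. The splits with 2803 and 2006 calls point to a structure of the samples, the latter with all 4 libraries lettered C among the regrouped hybrids. With the letter as a block and splits within letters, 1 of 41 splits, the real one, called as many genes for C24 against Ler (8840, highest other 2981), the mid-parent (614, highest other 2) and genes beyond both parents (187, highest other 1). Within letters no other split called as many genes, though these splits mix parents and hybrids in the same way. The split with 2981 calls kept 5 of 7 C24 and 6 of 7 Ler libraries in their place.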

How the results depend on the processing

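There were 7 kinds of fit chosen after seeing the data: those without Ler D and Ler E, the block without letter C, the block with the 2 unlettered columns as F and G, the arithmetic mid-parent with the block, the arithmetic mid-parent for differences between families, gene lists and positions without letter C, and shared genes with the block or from libraries outside letters A to C. The other fits were planned. Unless said otherwise, the cause of a change was not tested.

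RLE normalization left the 14 counts of genes within 1.5 times and the 132 values of named genes on their side of the threshold. Without a count filter 131 of 132 kept it, and C24/Ler hybrids had 0 genes beyond both parents in place of 1. With limma-voom on the log scale 97 mid-parent values of named genes kept it and 5 were lost, and the counts were 79, 373 and 346 for 71, 369 and 334. DESeq2 kept 125 of 132 and added 7. It called 2269 genes between C24 and Ler (for 1472), 165 against the C24/Ler mid-parent (for 71) and 3 beyond both (for 1). For C24/Col and Col/Ler hybrids it called 786 and 634 (for 369 and 334), 86 and 18 beyond both (for 41 and 3), and 19 and 4 between reciprocal crosses (for 0 and 0). Deviations that differed between families were 212 and 263 (for 122 and 126).

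With the letter as a block 118 of 132 named values kept their side, 13 were added and 1 was lost, and of the gene lists 47 of 54 kept it, 5 were added and 2 lost. The values changed are given in the report, and the block changed no other call. Counts rose to 8840 for C24 against Ler, 614 for the C24/Ler mid-parent and 187 beyond both, and C24xLer against LerxC24 fell to 0. C24 against Col rose to 6460 (for 3949) and Col against Ler to 7020 (for 4143). C24/Col and Col/Ler hybrids had 2214 and 1258 genes off the mid-parent and 475 and 155 beyond both parents, C24xCol against ColxC24 had 5, and deviations differed in 204 and 269. Shared genes rose from 110 to 605 (C24/Ler and C24/Col), from 105 to 498 (C24/Ler and Col/Ler) and from 129 to 648 (C24/Col and Col/Ler). With the 2 unlettered columns as F and G the first 4 counts were 9084, 1826, 424 and 0.

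Without letter C, C24 against Ler was 3943, the C24/Ler mid-parent 187 and beyond both 9, and 35 of 36 named values kept their side. Of 18 lists 16 kept it and the ethylene list was lost (adjusted p = 0.161), and with the block the defence list (0.115) and floral organ markers (0.0846) were lost and 2 lists were added. With the block as well these counts were 10037, 605 and 179, and C24xLer against LerxC24 was 0. The flowering list of C24/Ler hybrids pointed down by camera in all 24 libraries (median -0.11) and up without letter C (median -0.11, adjusted p = 0.0316) and without letter C with the block (median -0.0396, adjusted p = 0.00466). Letters A and B alone gave 4794, 305, 21 and 0 for the same 4 counts, and AT2G11240 came to 0.10 in C24 against Ler (for -9.03).

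Without Ler D and Ler E, C24/Ler hybrids had 0 genes beyond both and C24xLer against LerxC24 had 0, with 1478 and 95 for the parents and the mid-parent. With the block these 4 counts were 8116, 679, 182 and, between the reciprocal crosses, 0. Leaving out letter C as well, without the block, gave 4220, 227 and 5. Of 18 lists 15 kept their side without Ler D and Ler E and 3 were added: cell wall (adjusted p = 0.0211), glucosinolate (0.00587) and anthocyanin genes (0.0467). With the block as well 14 kept it, 2 were lost and 2 were added.

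With all 34 libraries in 1 fit the counts were 114 for the C24/Ler mid-parent and 2 beyond both, 1158 and 683 for C24 against Col and Col against Ler, 35 and 20 for the C24/Col and Col/Ler mid-parents, 1 and 0 beyond both, and 16 and 9 for deviations between families. Shared genes fell to 16, 5 and 10 in the order above. Of the named values 87 of 132 kept their side and 45 were lost, and of the lists 48 of 54 kept it, 2 were added, 2 lost and 2 turned. Jasmonate genes in C24/Col hybrids were called with a median of 0.28 (for -0.04, adjusted p = 0.00664), and glucosinolate genes in Col/Ler hybrids, where camera had pointed up, were called lower (median -0.44 for -0.28, adjusted p = 7.38e-06).

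The arithmetic mid-parent lies above the log-scale one by its construction, which lowers the values of genes with unlike parents. In C24/Col hybrids HSP101 (-0.43 and -0.44) and MYB12 (-0.60 and -0.61) lost their call at nearly the same value, and genes called lower went from 68 to 40. The cause of such losses was not tested. The arithmetic mid-parent gave 4, 75 and 98 genes for 71, 369 and 334, and with the block 403, 1787 and 825, with 467, 386 and 432 shared genes in the order above. Deviations between families fell from 122 and 126 to 2 and 9, and to 7 and 38 with the block. Of the named values 67 kept their side, 22 were lost and 13 turned, and with the block these were 65, 13 and 13, with 11 added. Those that turned are given without and with the block. In C24/Ler hybrids they were AT4G07965 (-0.29 and -0.0895), ARGAH2 (-0.50 and -0.62), AT2G15160 (-0.33 and -0.35) and AOP2 (-0.54 and -0.61). In C24/Col hybrids they were AT1G76960 (-0.00583 and -0.00546), ESP (-0.00595 and -0.00586) and AOP2 (-0.57 and -0.57, the latter with adjusted p = 0.0211). In Col/Ler hybrids they were AT4G07825 (-0.11 and -0.10), AT4G08110 (-0.0271 and -0.028), AT2G09795 (-0.0694 and -0.0686), SADHU1-1 (-0.0626 and -0.0574), TGG2 (-0.0079 and -0.00792) and AOP3 (-0.36 and -0.36).

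With letter C in the C24/Ler hybrids and no library shared, 11 genes were shared with C24/Col and 7 with Col/Ler hybrids, and 39 and 20 from the libraries outside letters A to C. With an estimated correlation 0 of 54 list tests were called, for 20. The median position over genes moved by less than 1 SD between libraries, with 0.529 after the letters were swapped, 0.511 at 4-fold, 0.516 at 5 CPM, 0.510 without letter C and 0.477 without Ler D and Ler E. The mean of the hybrid libraries' medians went from 0.504 to 0.453 without Ler D and Ler E, by more than 1 SD (0.0443).

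Fits that left out 1 library assume, where 1 is left, that it varies like the other groups. They gave 1203 to 1687 genes for C24 against Ler, 2662 to 3920 for C24 against Col and 2212 to 4105 for Col against Ler. Against the mid-parent they gave 59 to 97 (C24/Ler), 236 to 666 (C24/Col) and 187 to 356 (Col/Ler), and beyond both parents 0 to 2, 12 to 63 and 1 to 14. Between reciprocal crosses they gave 0 to 1 (C24xLer and LerxC24), 0 to 143 (C24xCol and ColxC24) and 0 to 1 (ColxLer and LerxCol), and 78 to 125 and 89 to 154 for deviations between families. Of the named values 2451 kept their side, 134 were lost, 7 were added and 0 turned. Changes of 1.5-fold were recovered for 16.4% of simulated genes in the 24 libraries and 47.8% in the 18. With the block these shares were 79.1% and 77.6%. Each simulation used the spread that its own fit estimated, so it cannot show whether the calls added by the block in the data are true.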

Other observations

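The tests of sulphur and glucosinolate genes in libraries not used to find them were set before their results were seen. The test of Ler D and Ler E was chosen after.

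Genes that seedlings switch on when sulphur is short were lower in hybrids of letters A and B with the letter as a block. The set was drawn up after some of its members had been seen. In C24/Col hybrids 12 of 17 fell (median -1.06), among them LSU1 (-1.74), LSU2 (-2.17), SDI1 (-2.00), SDI2 (-1.49), APR1 (-1.30) and SHM7 (-1.24). In C24/Ler hybrids 9 fell (median -0.61), such as SDI1 (-1.27) and SULTR4;1 (-0.54), while with all lettered libraries and the block 1 did (LSU3, -1.17; median -0.59), and in Col/Ler hybrids 7 (median -0.40), such as BGLU28 (-2.14), SDI1 (-1.02) and LSU2 (-1.01). The C24/Ler libraries outside letters A to C played no part in finding this. Their hybrids were C24xLer D and E and the unlettered LerxC24 U1 and U2, and their parents had letters D to G. There 16 of 17 were negative with a median of -1.12 (camera p = 0.00753 with an estimated correlation), while 0 passed singly with edgeR. The parents include Ler D and Ler E. The hypothesis that the lower level is a property of the hybrids and not of letters A and B alone passed this test, and a difference in sulphur supply between plates was not tested.

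Genes of aliphatic glucosinolate synthesis were lower in the same hybrids, with medians of -0.71 in Col/Ler (5 of 9 fell), -0.36 in C24/Ler (3 fell) and -0.19 in C24/Col hybrids (2 fell and 1, MAM3, rose). With an estimated correlation camera gave p = 0.00111, p = 0.0255 and p = 0.243 in that order, and p = 0.0884 in C24/Ler hybrids with all lettered libraries and the block, where 0 fell singly with edgeR (median -0.21). These libraries include letters A and B, where the fall was seen, so these p-values are no separate test of it. In the C24/Ler libraries outside letters A to C, with U1 and U2 among the hybrids, the median was -0.29. That is short of the bound of -0.3 set for it and beyond that of -0.1, so the libraries not used to find this leave it undecided. Against the mid-parent of the same letter the median of these genes was 0.10 in letter D, -0.00906 in E and -0.0576 in C, each above the bound of -0.1, against -0.41 in A and -0.30 in B, so it was below that bound in letters A and B alone, though the values of D and E rest on Ler D and Ler E. The sulphur set was at -0.74 in letter D, -0.78 in E and -0.23 in C by the same measure.

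Ler D and Ler E held transcripts that were near 0 in the other Ler libraries. For 17 genes expressed in C24 and Col the medians were 45.1% and 34.2% of the level there, and for 7 genes expressed in Col alone 19.95% and 11.7%, against at most 2.67% in the other Ler libraries. Of 18 genes expressed in C24 alone, 5 in Ler D and 3 in Ler E were above 10% (medians 1.87% and 1.37%). If RNA of plants of another genotype were present, genes expressed in Ler alone would be lower there. They stood at 53.2% in Ler D and 80.5% in Ler E, against 97.3% to 138% in Ler A, B, F and G and 81.5% in Ler C, which was left out of this test. The higher of these values, 80.5%, goes with such a mixture as a hypothesis. Medians of 1.87% and 1.37% for genes of C24 alone, beside 45.1% and 34.2%, argue against C24 as the main source. Some genes of C24 alone were above 10%, so a part from C24 is not excluded, and the genotype otherwise stays open. In LerxC24 A the 7 genes of Col alone had a median of 7.61%.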
